A study of Mus musculus with 27 samples.

How the data were processed

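Expression was measured on 27 mouse gene arrays in 9 groups of 3, as the labels give them: the 5 titration groups of starburst and cone cells, the 3 X mixtures and the Arc-EGFP amacrine cells. According to the study's design, 2 retinas of the cone line and 6 of the starburst line were pooled, the titration mixtures were sorted from the pool, and this was done 3 times from different mice. It does not say outright whether each X mixture came from the same pools, so replicate number was not a term of the main model. The deposited values are log2 values made by the authors with RMA (background correction, normalization between arrays and summary per probe set) using the R package oligo in R 2.11.1, with genome build mm9 named, per the submitters' processing notes. The notes do not name the arrays normalized together. The values were checked: medians of the arrays lay between 2.78 and 2.89, and 0 pairs of arrays were identical. Total counts do not apply to arrays, and the number of arrays limits the precision.

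Of 22347 probe sets, 19446 carried 1 gene symbol, 735 several and 2166 none in the probe table, and the last 2 kinds were left out of the gene tests. For the 133 genes with several probe sets the one with the highest mean was used. Among them 0 genes had probe sets called in opposite directions by limma and 13 had one called and another not. Of 19301 genes, the 12441 above the median of all values (2.83) in at least 3 arrays were tested. Symbols were matched to current ones by their Entrez numbers for 19368 probe sets, and 0 changed.

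All 27 arrays entered 1 fit with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, 18 residual degrees of freedom, prior degrees of freedom 3.42). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes and an absolute log2 fold change of at least 1. The comparisons were pure cone against pure starburst, Arc amacrine cells against each of these, 5 mixtures against the pure group closest in composition, and a slope on cone share over the 15 titration arrays. All tests were two-sided. Genes named in the text followed a rule: the 12 called genes with the largest fold change in each direction and with groups that did not overlap, the 5 called genes with the largest absolute fold change for each mixture, the called list members with the largest folds with up to 2 uncalled members of high level, and the brightest and the most curved 5 cell-type genes; predicted genes without a name were only counted. Chat, Chrnb4 and Arc were always given. Gnat1, Gnb1, Cnga1, Pde6b, Sag, Reep6, Nrl and Slc24a1 on the third arrays, Eif2s3y and Xist, and the called members of lists that did not pass camera were named after their values were seen.

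The 33 gene lists held 531 genes, of which 475 were measured and 375 tested, and 31 lists had at least 3 tested genes. They cover retinal cell types, transmission, metabolism, stress, cilia, disease and housekeeping genes, and were written from textbook knowledge. Lists share genes, such as Isl1 (starburst and bipolar) and Calb1 (amacrine and horizontal). For each list, members called over all genes and adjusted over the list alone were counted, and limma's camera was run with a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. Pigq entered the glycolysis list through a synonym of the listed Gpi1 and is no glycolysis gene, which was seen later. Camera called 15, 13 and 13 lists in the 3 comparisons of cell types, 10, 13 and 13 without Pigq, and 9, 3 and 7 with an estimated correlation. Limma's fry, which tests whether a list's genes move one way and does not compare them with other genes, called 19, 13 and 24.

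For the mixtures, log2 values were turned back to the linear scale. Cell-type genes were those called between the pure groups with an absolute log2 fold change of at least 2 (276 genes). An array's position was the mean of 2 medians, over cone-high and starburst-high genes, of its distance from the pure starburst mean in percent of the distance between the pure means. The log2 RNA yield ratio compared the odds of the position with the odds of the stated share, with an exact sign-flip test over 9 arrays, which come from 3 pools, so means by replicate number were taken as well. The straight line was fitted to 5 group means, and curvature was tested by limma with a quadratic contrast. Correlations had permutation p-values from 1e+05 resamples. The intervals on shares of genes are Wilson intervals at 95%.

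The steps were tested on simulated data with the spread of these arrays. For pure cone against pure starburst, with 50 genes at each fold among 12441, 36%, 90%, 98% and 100% of genes with a true log2 fold of 1, 2, 3 and 4 were recovered, and limma called 6 unchanged genes. Of 4 lists shifted there, camera, camera with an estimated correlation and fry each called 4, and of 27 unshifted lists 2, 2 and 3, all of which shared genes with a shifted list. The slope over the titration recovered 94.9% of 312 genes with a true log2 fold of 2 or more. A true log2 yield ratio of 0 was read as -0.08 and one of -1 as -1.04. In the mixtures with 157, 75 and 183 cone cells, true cone RNA shares of 78.5%, 37.5% and 91.5% were read as 73.0%, 37.3% and 85.0%, so high cone shares read low. Curvature was called in 1 of 368 simulated cell-type genes at a ratio of 0 and in 16 of 349 at -1, where unequal RNA per cell bends the line.

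The groups, comparisons, thresholds, lists, naming rule and all alternatives but 2 were chosen before the data were examined. The alternatives fixed then were no filter and a stricter filter on dim genes (75th percentile), the mean of a gene's probe sets, centring each array on its median, quantile normalization again, only the 2 groups compared, eBayes with or without an intensity trend, array weights, an adjusted p under 0.01, no fold threshold, a replicate block, each array left out in turn, and, for the mixtures, other folds for the cell-type genes, each direction alone, a floor on linear values, least squares, end points from other replicates, the log2 scale and the X mixtures added to the slope. Leaving out the third arrays of the 7 groups with cone cells, and Pigq from its list, were added after the data were seen. Whether replicate numbers pair the arrays was checked by correlating, for each number, the deviations of both groups from their means over genes. The correlation was above 0.1 for all 3 numbers only for the mixture with 17 starburst cells against pure cone, where the highest between different numbers was 0.129.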

Results

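Gene expression was measured on 27 arrays, each from 200 cells sorted by fluorescence from dissociated adult mouse retina. Cone photoreceptors carried GFP under the control of the Chrnb4 locus. Starburst amacrine cells, the cholinergic interneurons of the retina, carried RFP switched on by Chat-driven Cre recombinase. A titration of 5 groups held starburst and cone cells at 200 and 0, 150 and 50, 100 and 100, 50 and 150, and 0 and 200. Another 3 groups, called the X mixtures here, held 43 starburst with 157 cone cells, 125 with 75, and 17 with 183. The ninth group held amacrine cells labelled by Arc-EGFP and served in the study as an internal control between batches. Cone and starburst cells came from different mouse lines by the design, and the Arc cells carried another reporter. A difference between cell types therefore cannot be told apart from one between lines. The labels name an inherited photoreceptor degeneration for the background of some mice. Each group had 3 replicate arrays, and this number limits the precision of every value below. Correlations between replicates of a group lay between 0.919 (2 pure cone arrays) and 0.973 (2 Arc arrays). Genes were called different at a limma adjusted p under 0.05 with an absolute log2 fold change of at least 1, over 12441 tested genes. Errors of fold changes are standard errors (SE) from the limma fit over all 27 arrays, with n = 3 arrays per group. They carry the residual spread of all groups after eBayes, not that of the 2 groups compared alone. The filter for dim genes lay at 2.83, and a fold against a group under that level depends on the background. This held for 3 of the 24 genes with the largest folds between cones and starburst cells (Apela, Pde6c and Sox2), 8 of 24 between the Arc cells and starburst cells (Lor, Vip, Plppr5, Gdpd3, Calb2, Slc10a4, Calb1 and Sox2) and 4 of 24 between the Arc cells and cones (Cbln1, Wfikkn2, Apela and Pde6c).

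Pure cone arrays were first compared with pure starburst arrays, the ends of the titration. Genes of cone phototransduction were the highest on the cone side. The medium-wave opsin Opn1mw was higher by 6.25 ± 0.59 on the log2 scale (adjusted p = 1.3e-07), the short-wave opsin Opn1sw by 6.23 ± 0.95 (7.4e-05), and the cone transducin subunit Gnat2 by 6.10 ± 0.83 (1.9e-05). On the starburst side, the vesicular acetylcholine transporter Slc18a3 differed by -7.50 ± 0.23 (4.8e-16), the calcium-binding calretinin Calb2 by -6.93 ± 0.19 (1.4e-16), and Slc10a4, a transporter of cholinergic vesicles, by -5.32 ± 0.19 (1.7e-14). Other genes with high folds in cones were the cone arrestin Arr3 (5.88), the cone phosphodiesterase subunits Pde6h (5.79) and Pde6c (5.54), the acyltransferase Mogat1 (5.66), the secreted peptide Apela (5.64), the transducin subunit Gnb3 (5.59), Mpp7 (5.07), Ppm1j (4.56) and the potassium channel subunit Kcne2 (4.27). Those in starburst cells were the glutathione transferase Gsto1 (-5.57), the growth factor binding proteins Igfbp7 (-5.18) and Igfbp6 (-4.68), Cmtm8 (-5.13), Ube2ql1 (-4.81), the potassium channel subunit Kcnmb4 (-4.78), the neuropeptide Cck (-4.73), the transcription factor Sox2 (-4.70) and the synaptic scaffold Homer2 (-4.64). In all, 1048 genes were called, 328 higher in cones and 720 higher in starburst cells. The genes that drive the reporters differed by less. Chat was lower in cones (-1.04 ± 0.22, 0.0026), but its fold fell under the threshold without pure cone replicate 2 (-0.95) or pure starburst replicate 3 (-0.78). Chrnb4 was higher in cones (1.35 ± 0.44, 0.045), with an adjusted p of 0.0505 in the replicate block. Its adjusted p was 0.185 without pure cone replicate 1, 0.116 without pure cone replicate 2, and 0.0944, 0.162 and 0.0525 without pure starburst replicates 1, 2 and 3, and it was 0.0629 with no filter on dim genes. Arc itself did not pass (0.19 ± 0.14, 0.437).

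Photoreceptor lists stood higher in cones. Of 15 tested cone photoreceptor genes, 11 were higher and 4 not called (12 adjusted over the list alone), with Opn1mw, Opn1sw, Gnat2 and Arr3 as the highest folds, while Ccdc136 (1.02, 0.185) and the channel Kcnv2 (0.63, 0.0032) were not called. The camera test gave an adjusted p of 5.8e-18, and the adjusted p was 0.0289 with an estimated correlation. The pan-photoreceptor list had 18 of 20 genes higher (18 adjusted over the list alone), among them the calcium sensor Rcvrn by 3.42 ± 0.44, the complexin Cplx4 by 3.39 ± 0.29 and Aipl1, a chaperone of phosphodiesterase, by 3.18 ± 0.54 (camera 3.5e-30). Of 27 tested genes of inherited cone and rod disease, 16 were higher (17 adjusted over the list alone, camera 2.6e-18), with Gnat2, Pde6h, Pde6c and Aipl1 first. Rod photoreceptor genes were higher for 4 of 13 and not called for 9 (4 adjusted over the list alone, camera 9.4e-09, adjusted p = 0.0342 with an estimated correlation). The called members were the arrestin Sag (2.79 ± 0.27), the phosphodiesterase subunit Pde6g (2.73 ± 0.23), the disc rim protein Rom1 (1.97 ± 0.22) and the transducin subunit Gngt1 (1.73 ± 0.23). The rod transducin subunit Gnat1 was not called (1.10 ± 0.53, 0.190) and read 8.11 and 8.28 on the first and second pure cone arrays and 10.4 on the third. Ribbon synapse genes were higher for 9 of 15 (9 adjusted over the list alone, camera 3.9e-13), led by Cplx4, Cplx3 (2.34 ± 0.43) and the calcium channel Cacna1f (2.20 ± 0.36). Cilium and intraflagellar transport genes were higher for 3 of 18 (3 adjusted over the list alone, camera 0.0019, adjusted p = 0.0838 with an estimated correlation). These were Bbs9 (2.13), Ift57 (1.95) and the transition zone protein Cep290 (1.48 ± 0.20). Bbs9 lost its call without pure cone replicate 1 (adjusted p = 0.0927) or 2 (0.0772) and without pure starburst replicate 1 (0.0602) or 2 (0.0705), and Ift57 without pure cone replicate 2 (0.0754) or pure starburst replicate 2 (0.0551).

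Starburst amacrine genes were lower in cones for 6 of 12 and not called for 6 (6 adjusted over the list alone, camera 3.3e-10), with Slc18a3, Sox2, the transcription factor Isl1 (-4.63 ± 0.39) and the potassium channel Kcnc2 (-1.88 ± 0.23) first, and Ache (0.21, 0.820) among those not called. Of 15 pan-amacrine and GABAergic genes, 8 were lower, 1 higher and 6 not called (the same counts adjusted over the list alone, camera 2.0e-08), including Calb2, the calcium-binding calbindin Calb1 (-4.43 ± 0.33), the GABA-synthesising enzyme Gad1 (-3.01 ± 0.28) and the transcription factor Tfap2b (-2.88 ± 0.24). GABA-A and glycine receptor genes were lower for 3 of 8 (4 adjusted over the list alone, camera 0.0019), namely Gabrb1 (-2.67), Gabra4 (-2.36) and Glrb (-1.36). Horizontal cell genes were lower for 3 of 8 (3 adjusted over the list alone, camera 0.0010). These were Calb1, which the amacrine list also holds, the sodium pump subunit Atp1b1 (-2.20) and Septin4 (-1.55). Ionotropic glutamate receptor genes were lower for 2 of 6, Gria4 (-1.64) and Gria2 (-1.37) (2 adjusted over the list alone, camera 0.0473). That call was lost with an adjusted p = 0.102 with an estimated correlation, and at 0.0502 in the replicate block. The glycolysis list, in which Pigq, a gene of another pathway, stands through a shared synonym, was lower for 3 and higher for 1 of 17 (the same adjusted over the list alone, camera 0.0473, adjusted p = 0.478 with an estimated correlation), with the lactate dehydrogenase Ldhb (-2.22) and the phosphofructokinase Pfkm (-1.88) first. Cytosolic ribosomal protein genes were lower for 1 of 19, Rpl14 (-1.38) (1 adjusted over the list alone, camera 0.0479). This call was lost with an adjusted p = 0.251 with an estimated correlation, and at 0.0502 in the replicate block. Nicotinic and muscarinic receptor genes were higher in cones for 3 of 8 (3 adjusted over the list alone, camera 0.0473, adjusted p = 0.0838 with an estimated correlation), namely Chrna5 (2.45), Chrna3 (1.49) and Chrnb4. Chrna5 lost its call without pure cone replicate 1 (0.126) or 2 (0.187) and without pure starburst replicate 1 (0.114), 2 (0.0965) or 3 (0.0665), and Chrna3 without pure cone replicate 1 (0.0699) or 2 (0.0631). Bipolar cell genes were higher for 3, lower for 1 and not called for 11 of 15 (4 and 1 adjusted over the list alone, camera 0.0473, adjusted p = 0.478 with an estimated correlation). Isl1 was the lower one and the calcium-binding Cabp5 (2.56 ± 0.38) the highest. Without the filter on dim genes the ionotropic glutamate receptor (camera 0.472), nicotinic and muscarinic receptor (0.166) and bipolar (0.0946) lists were not called. With Pigq taken out, the adjusted p was 0.0699 for glycolysis, 0.0505 for the bipolar and the nicotinic and muscarinic receptor lists, 0.0509 for ionotropic glutamate receptors and 0.0513 for ribosomal proteins, so that 10 lists in place of 15 were called.

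The other lists did not pass camera between cones and starburst cells. No gene was called among 9 glycinergic and other amacrine genes (limma, camera 0.813), 7 microglia and macrophage genes (0.409), 6 pigment epithelium genes (0.447) and 28 oxidative phosphorylation genes (0.586). Single genes were called among the retinal ganglion cell (1 of 10; 0.813), Muller glia (1 of 15; 0.724), astrocyte (1 of 6; 0.497), vascular and pericyte (1 of 4; 0.143), immediate early (1 of 19; 0.149) and housekeeping (1 of 11; 0.642) lists. The Muller list's gene was the receptor Gpr37 (-3.42 ± 0.20) and the vascular list's gene the adhesion protein Vtn (2.82 ± 0.42). Heat shock genes had 2 of 11 called (0.514), voltage-gated potassium channels 2 of 16 (0.673), voltage-gated sodium and calcium channels 2 of 7 (0.885), neuropeptides 3 of 13 (0.813), cadherins and protocadherins 3 of 16 (0.883) and synaptic vesicle and SNARE genes 5 of 22 (0.879). Median, mean and test differed in sign for the last list (median -0.19, mean 0.10, test down), for sodium and calcium channels (-0.30, 0.18, up), neuropeptides (0.10, -0.14, down) and cadherins (0.03, -0.11, down).

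**Figure D1:**
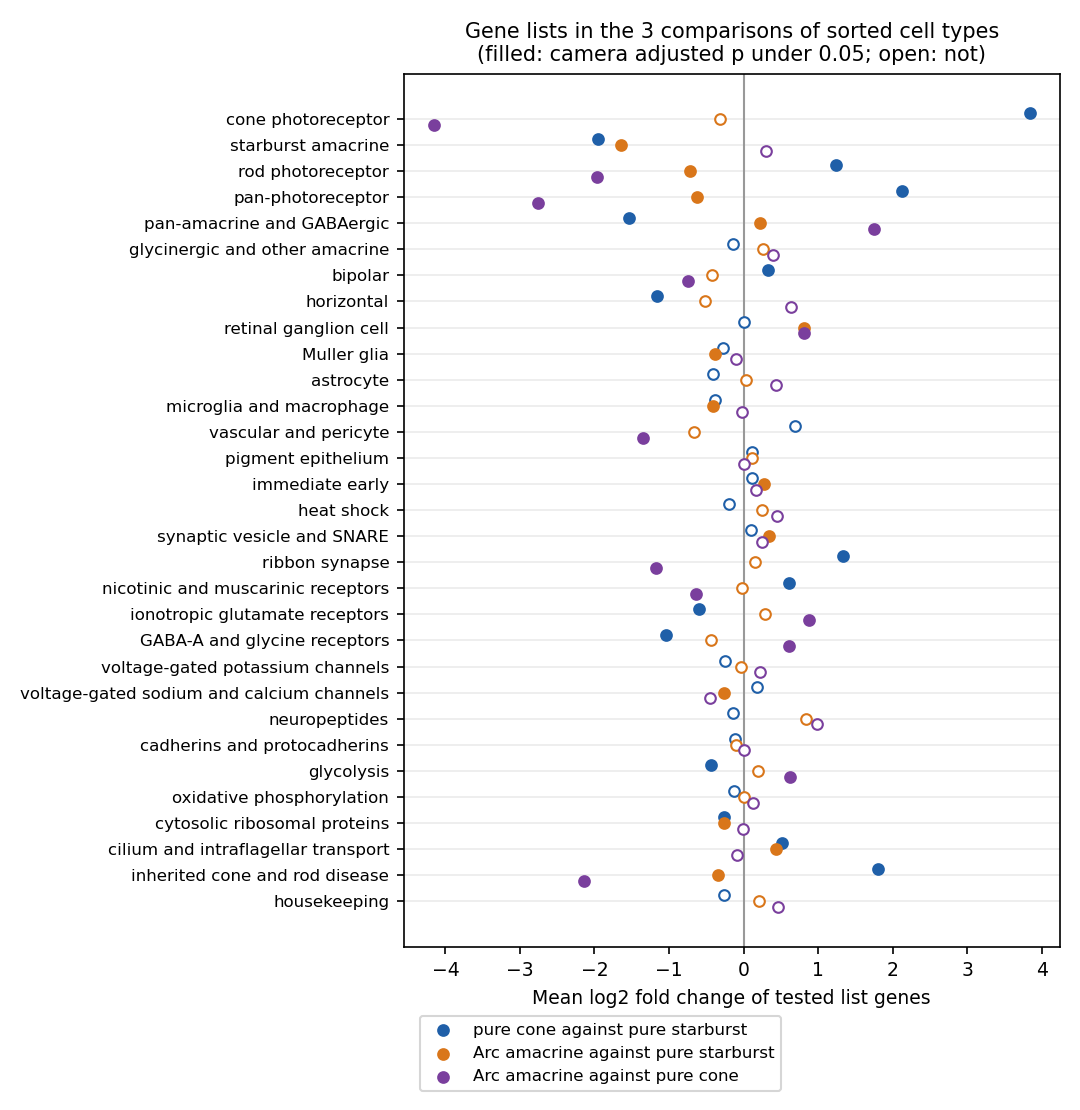
Mean log2 fold change of the tested genes of each fixed list (x axis) for 31 lists (y axis) in the 3 comparisons of sorted cell types. Filled points had a camera adjusted p under 0.05 and open points did not; the cone photoreceptor list had means of 3.84 (pure cone against pure starburst), -0.32 (Arc amacrine against pure starburst) and -4.16 (Arc amacrine against pure cone).

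Arc-EGFP amacrine cells were then compared with pure starburst cells, another amacrine type. Loricrin, Lor, had the largest fold in the Arc cells (6.51), where the neuropeptide precursor Cartpt was higher by 5.76 ± 0.75 (1.9e-05), vasoactive intestinal peptide Vip by 5.09 ± 0.30 (4.1e-11), the somatostatin receptor Sstr2 by 4.97 ± 0.29 (5.3e-11) and the substance P precursor Tac1 by 4.94 ± 0.80 (2.5e-04). Higher in the starburst cells were Slc18a3, which differed by -7.57 ± 0.23 (4.0e-16), and Slc10a4, by -5.98 ± 0.19 (1.4e-15). Other high folds in the Arc cells were those of Frmd5 (4.77), the secreted synapse organisers Cbln2 (4.67) and Cbln1 (4.60), Plppr5 (4.39), Igfbp2 (4.36) and Gdpd3 (3.85). Mpp7 (4.67) was called as well, but not without pure starburst replicate 1 (adjusted p = 0.0533). Other genes higher in starburst cells were Calb2 (-7.01), Isl1 (-5.75), Kcnmb4 (-5.69), Cmtm8 (-5.67), Cck (-5.02), Igfbp7 (-5.00), Igfbp6 (-4.82), Calb1 (-4.71), Sox2 (-4.55) and Nupr1 (-4.37). Of the reporter genes, Arc was higher in the Arc cells (1.47 ± 0.14, 1.7e-07) and Chat lower (-1.23 ± 0.22, 9.4e-04; log2 fold change -0.98 without pure starburst replicate 3), and Chrnb4 did not pass (-0.25 ± 0.44, 0.882). Arc averaged 4.54 on the Arc arrays, while Chat (2.85) and Chrnb4 (2.46) lay near or under the filter for dim genes. In all, 442 genes were called, 269 higher and 173 lower in the Arc cells.

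Of 12 starburst genes, 7 were lower, 2 higher and 3 not called in the Arc cells (7 and 2 adjusted over the list alone, camera 1.1e-10), with Slc18a3, Isl1 and Sox2 down and the acetylcholine-degrading enzyme Ache up (2.46 ± 0.44). Cytosolic ribosomal proteins passed camera (2.6e-06, adjusted p = 0.0171 with an estimated correlation) with 0 of 19 genes called by limma, and among them Rps14 differed by -0.29 (0.128) and Rpl6 by -0.35 (0.0907). Retinal ganglion cell genes were higher for 2 of 10, the growth-associated protein Gap43 (3.64 ± 0.24) and the surface protein Thy1 (2.52 ± 0.37) (2 adjusted over the list alone, camera 0.0087, adjusted p = 0.0429 with an estimated correlation). Those 3 lists were the ones called with an estimated correlation. Pan-amacrine and GABAergic genes were higher for 4, lower for 2 and not called for 9 of 15 (the same adjusted over the list alone, camera 0.0071, adjusted p = 0.207 with an estimated correlation), with Calb2 and Calb1 down and the GABA-synthesising enzyme Gad2 (3.53 ± 0.24) and the RNA-binding protein Elavl4 (3.38 ± 0.28) up. The pan-photoreceptor list had 5 of 20 genes lower in the Arc cells (5 adjusted over the list alone, camera 4.2e-07, adjusted p = 0.163 with an estimated correlation), with Cplx4 (-1.70 ± 0.29) and the guanylate cyclase activator Guca1a (-1.66 ± 0.33) first. The rod list had 2 of 13 lower (2 adjusted over the list alone, camera 6.1e-05, adjusted p = 0.186 with an estimated correlation), Rom1 (-1.44 ± 0.22) and Gngt1 (-1.02 ± 0.23). The Gngt1 fold change was -0.92 without Arc replicate 1, -0.86 without Arc replicate 2 and -0.93 without pure starburst replicate 2, so that its call was lost. The disease list had 2 of 27 lower (2 adjusted over the list alone, camera 0.012, adjusted p = 0.366 with an estimated correlation). These were Guca1a and the retinol dehydrogenase Rdh12 (-1.24), which lost its call without Arc replicate 3 (0.0537) or pure starburst replicates 1 (0.0588) or 2 (0.0803). The cone list itself was not called (0 of 15 by limma, camera 0.259).

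Immediate early genes were higher in the Arc cells for 2 of 19, the nuclear receptor Nr4a2 (1.78 ± 0.16) and Arc (2 adjusted over the list alone, camera 0.01, adjusted p = 0.149 with an estimated correlation). Muller glia genes had 1 higher and 2 lower of 15 (2 and 2 adjusted over the list alone, camera 0.0328, adjusted p = 0.366 with an estimated correlation), with Gpr37 (-3.28 ± 0.20) and the secreted Dkk3 (1.63 ± 0.23) first. Synaptic vesicle and SNARE genes had 1 higher, Cplx3 (3.34 ± 0.43), and 1 lower, Cplx4, of 22 (2 and 1 adjusted over the list alone, camera 0.0328, adjusted p = 0.0837 with an estimated correlation). Cilium genes were higher for 3 of 18, led by Ift57 (1.94) and the kinesin Kif3a (1.55 ± 0.32) (3 adjusted over the list alone, camera 0.042, adjusted p = 0.289 with an estimated correlation). Ift57 lost its call without Arc replicate 1 (0.0597) or 3 (0.0926) and without pure starburst replicate 2 (0.107) or 3 (0.0546). Voltage-gated sodium and calcium channels (0 of 7 called by limma, 1 lower adjusted over the list alone, camera 0.0428) lost the list's call with an adjusted p = 0.186 with an estimated correlation, and at 0.0594 in the replicate block. Microglia and macrophage genes (0 of 7 called by limma, 1 lower adjusted over the list alone, camera 0.041) had an adjusted p = 0.236 with an estimated correlation. Neuropeptides had Cartpt, Vip and Tac1 up and 2 of 13 down, Cck first (camera 0.465), and glycinergic and other amacrine genes had 2 of 9 up, the dopamine-synthesising enzyme Th (2.15 ± 0.25) and the transcription factor Lhx9 (1.80 ± 0.25) (camera 0.513).

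Without the filter on dim genes the cilium (camera 0.0861) and sodium and calcium channel (0.624) lists were not called. The remaining lists did not pass camera with the filter either, namely bipolar (2 of 15 called; 0.207), horizontal (1 of 8; 0.207), ribbon synapse (2 of 15; 0.763), ionotropic glutamate receptors (1 of 6; 0.342), GABA-A and glycine receptors (3 of 8; 0.173), vascular and pericyte (1 of 4; 0.119), potassium channels (1 of 16; 0.883) and cadherins (3 of 16; 0.447). Limma called 0 genes in the astrocyte (camera 0.513), pigment epithelium (0.829), heat shock (0.191), nicotinic and muscarinic receptor (0.717), glycolysis (0.173), oxidative phosphorylation (0.71) and housekeeping (0.207) lists. Signs differed for potassium channels (median 0.07, mean -0.03, test up), cadherins (0.05, -0.10, down), astrocyte (-0.0052, 0.03, up) and oxidative phosphorylation genes (0.04, 0.0003, down).

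The Arc cells were also compared with pure cones. Klhl32 was higher in the Arc cells by 5.32 ± 0.86 (1.2e-04), Cbln1 by 5.07 ± 0.42 (1.6e-08), Sstr2 by 4.89 ± 0.29 (1.3e-10) and Vip by 4.67 ± 0.30 (3.1e-10). Phototransduction genes were higher in cones, since Opn1mw differed by -7.84 ± 0.59 (3.7e-09), Pde6h by -6.86 ± 0.59 (2.8e-08) and Gnat2 by -6.85 ± 0.83 (3.1e-06). Further genes of the Arc cells were Nudt11 (4.73), Ube2ql1 (4.58), Wfikkn2 (4.44), the neuronal Tagln3 (4.26), Lor (4.16), Frmd5 (4.09), Cartpt (4.06) and Igfbp2 (4.004). Further genes of cones were Arr3 (-6.67), Opn1sw (-6.38), Apela (-5.98), Gnb3 (-5.63), Pde6c (-5.57), Cplx4 (-5.09), Kcne2 (-4.92), Vtn (-4.73) and Mogat1 (-4.56). Arc was higher in the Arc cells (1.28 ± 0.14, 9.1e-07), Chat did not pass (-0.20 ± 0.22, 0.622), and Chrnb4 was lower (-1.60 ± 0.44, 0.014), with an adjusted p of 0.0779 without pure cone replicate 1. In all, 1286 genes were called, 974 higher in the Arc cells and 312 higher in cones.

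Cone photoreceptor genes were lower in the Arc cells for 11 of 15 (12 adjusted over the list alone, camera 4.6e-18, adjusted p = 0.0331 with an estimated correlation), pan-photoreceptor genes for 18 of 20 (18 adjusted over the list alone, camera 4.6e-36) and disease genes for 17 of 27 (17 adjusted over the list alone, camera 2.0e-21). Rod genes were lower for 6 of 13 (9 adjusted over the list alone, camera 1.2e-13), with Sag (-3.71 ± 0.27), Rom1 (-3.41 ± 0.22) and the phosphodiesterase subunits Pde6b (-3.35 ± 0.76) and Pde6g (-3.26 ± 0.23) first. Pde6b read 5.81, 6.24 and 8.50 on pure cone replicates 1, 2 and 3, so its fold rested partly on the third. The rod list averaged 7.08 on the pure cone arrays, 5.83 on the pure starburst arrays and 5.11 on the Arc arrays, with SDs of 0.63, 0.32 and 0.22 (n = 3). Ribbon synapse genes were lower for 8 of 15 (8 lower and 1 higher adjusted over the list alone, camera 2.2e-09), with Cplx4, the transport protein Unc119 (-2.60 ± 0.25) and Cacna1f (-2.23 ± 0.36) first. Pan-amacrine and GABAergic genes were higher for 10 of 15 (10 adjusted over the list alone, camera 9.3e-12), among them Tfap2b (3.66 ± 0.24), Elavl4 (3.29 ± 0.28), Gad1 (3.21 ± 0.28) and Gad2 (3.17 ± 0.24). Ionotropic glutamate receptors were higher for 2 of 6, Gria3 (1.95 ± 0.25) and Gria4 (1.76 ± 0.26) (2 adjusted over the list alone, camera 0.0088, adjusted p = 0.0411 with an estimated correlation).

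Bipolar genes were lower in the Arc cells for 5 and higher for 1 of 15 (the same adjusted over the list alone, camera 0.0015, adjusted p = 0.221 with an estimated correlation), with Scgn (-2.76 ± 0.56), the G protein subunit Gng13 (-2.65 ± 0.62) and Cabp5 (-2.60 ± 0.38) first. The glycolysis list with Pigq was higher for 5 and lower for 1 of 17 (the same adjusted over the list alone, camera 0.0044, 0.0070 without Pigq, adjusted p = 0.221 with an estimated correlation), led by the aldolase Aldoc (2.17 ± 0.18) and Ldhb (1.89 ± 0.33). GABA-A and glycine receptors were higher for 3 of 8, Gabra3 (1.57), Glrb (1.27) and Gabrb1 (1.18; 0.97 without Arc replicate 1) (3 adjusted over the list alone, camera 0.0432, adjusted p = 0.159 with an estimated correlation). Retinal ganglion cell genes were higher for 3 of 10, Gap43 (3.01), Thy1 (2.33) and the microtubule regulator Stmn2 (1.93) (3 adjusted over the list alone, camera 0.0419, adjusted p = 0.0753 with an estimated correlation). The vascular list had 1 of 4 genes lower, Vtn, a secreted adhesion protein (1 adjusted over the list alone, camera 0.0267, adjusted p = 0.0999 with an estimated correlation). Nicotinic and muscarinic receptors were lower for 2 of 8, Chrna5 (-2.68) and Chrnb4 (3 adjusted over the list alone, camera 0.0275, adjusted p = 0.0684 with an estimated correlation). Chrna5 lost its call without Arc replicate 1 (0.0677) or 2 (0.0551) and without pure cone replicate 1 (0.0739) or 2 (0.113). Without the filter on dim genes the ganglion cell (camera 0.234), vascular (0.224), nicotinic and muscarinic receptor (0.407) and ionotropic glutamate receptor (0.0648) lists were not called.

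The lists left did not pass camera between the Arc cells and cones: starburst amacrine (3 of 12 called; 0.489), glycinergic and other amacrine (2 of 9; 0.329), horizontal (3 of 8; 0.106), Muller glia (1 of 15; 0.245), astrocyte (1 of 6; 0.415), immediate early (4 of 19; 0.469), heat shock (1 of 11; 0.132), synaptic vesicle and SNARE (7 of 22; 0.0957), potassium channels (2 of 16; 0.517), sodium and calcium channels (2 of 7; 0.0957), neuropeptides (3 of 13; 0.131), cadherins (1 of 16; 0.553), ribosomal proteins (1 of 19; 0.172), cilium (2 of 18; 0.2) and housekeeping (1 of 11; 0.136). Limma called 0 genes among microglia and macrophage (0.489), pigment epithelium (0.471) and oxidative phosphorylation genes (0.698). Signs differed for microglia (median 0.08, mean -0.02, test down), pigment epithelium (-0.09, 0.0014, down) and cadherin genes (0.07, 0.01, down). The erythrocyte list had 1 tested gene and the sex-linked list 2, too few for a list test. The erythrocyte gene read 2.90 on pure starburst, 2.80 on pure cone and 2.95 on Arc arrays.

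Mixtures were compared with the pure group they lay closest to, to show how small an admixture could be read. Cone opsin and transduction genes marked an admixture of 50 cone cells among 150 starburst cells: Opn1mw was higher by 5.17 ± 0.59 (1.9e-04) and Pde6h by 4.81 ± 0.59 (3.1e-04). With 75 cone cells among 125, Opn1mw was higher by 4.43 ± 0.59 (0.0024). Starburst cells among cones were marked by Calb2 and Slc18a3. Calb2 was higher by 6.48 ± 0.19 (5.6e-16) and Slc18a3 by 6.27 ± 0.23 (2.1e-14) at 50 starburst cells, and Slc18a3 by 6.34 ± 0.23 (1.6e-14) and Calb2 by 5.75 ± 0.19 (7.1e-15) at 17. Against pure starburst, 6 genes were called for the mixture with 50 cone cells, all higher, and 741 had an unadjusted p under 0.05. Opn1sw (5.10), Gnat2 (4.85) and Arr3 (4.78) were among them. Each of these 3 lost its call without any one of the 3 replicates of the mixture or without pure starburst replicate 3 (adjusted p up to 0.187, 0.106 and 0.0792 respectively), and Opn1sw (0.121) and Arr3 (0.0899) also without pure starburst replicate 1. For the mixture with 75 cone cells, 6 genes were called, 2 higher and 4 lower, and 955 had an unadjusted p under 0.05. Pde6h (3.69) lost its call without replicate 1 of the mixture (0.0898) or pure starburst replicate 3 (0.0547). Of the lower genes, Fgl1 (-2.08) lost its call without each of the 6 arrays in turn (0.0564 to 0.0956) and in the replicate block (0.0534). Papolb (-1.27) lost it without any of the 3 replicates of the mixture (0.0685 to 0.135) or without pure starburst replicates 1 (0.0668) or 2 (0.114), and Tstd3 (-1.15) without replicates 1 (0.0898) or 3 (0.0677) of the mixture or pure starburst replicate 2 (0.0901).

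Against pure cones, 174 genes were called for the mixture with 50 starburst cells (154 higher and 20 lower), 192 for that with 43 (127 and 65) and 91 for that with 17 (81 and 10). Besides Slc18a3 and Calb2, the highest folds were those of Slc10a4 at 5.23, 4.97 and 4.45, and of Igfbp7 at 4.16, 4.13 and 3.66, in that order, of Gsto1 at 4.30 with 50 cells, and of Cmtm8 at 4.23 with 43 and 3.84 with 17. Slc18a3 and Calb2 were higher by 6.59 and 5.97 with 43 cells. Chat and Chrnb4 were not called in any of these 5 comparisons: Chat differed most with 50 starburst cells (0.54 ± 0.22, 0.326) and Chrnb4 with 50 cone cells (0.76 ± 0.44, 0.886). When only the 2 groups compared entered the fit, the counts were 36, 24 and 8 against pure cones, and 21 and 1 against pure starburst with 50 and 75 cone cells. In that fit Opn1mw (adjusted p = 0.205) and Pde6h (0.202) lost their calls with 75 cone cells, as did Igfbp7 against pure cones with 50 (0.159), 43 (0.151) and 17 (0.425) starburst cells and Cmtm8 with 17 (0.0762). Only for the mixture with 17 starburst cells were the correlations within all 3 replicate numbers above 0.1, the level set for paired arrays (0.197, 0.125 and 0.305), but the highest between different numbers was 0.129, and the replicate block called 104 genes there.

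The series asks whether expression follows the amount of RNA over the titration. With the cone share as a number over the 15 titration arrays, 1020 genes were called, 317 rising and 703 falling with cone share. Among the genes highest in their own pure group, the medium-wave opsin Opn1mw read 32.1 ± 29.2 (SD, n = 3, linear scale) on pure starburst arrays, 896 ± 86.5 with 50 cone cells, 1518 ± 53.1 with 100 and 1999 ± 745 on pure cone arrays. With 50 cone cells, a stated share of 25%, Opn1mw had reached 43.9% of its pure cone level above the starburst level, Pde6h 47.6%, Guca1a 45.2%, Gnat2 37.1% and Sag 24.4%. The median over all 101 genes higher in cones by a log2 fold change of at least 2 was 20.4%. Starburst genes still read high at small shares. With 17 starburst cells among 183 cones, the median over all 175 starburst-high genes was 24.97% of the pure starburst level above the cone level. The quartiles were 17.7% and 33.6%. Among the genes named for their brightness or curvature, Slc18a3 stood at 45.1%, Calb2 at 44.9%, Slc10a4 at 54.5% and the calmodulin regulator Pcp4 at 88.2%.

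**Figure D2:**
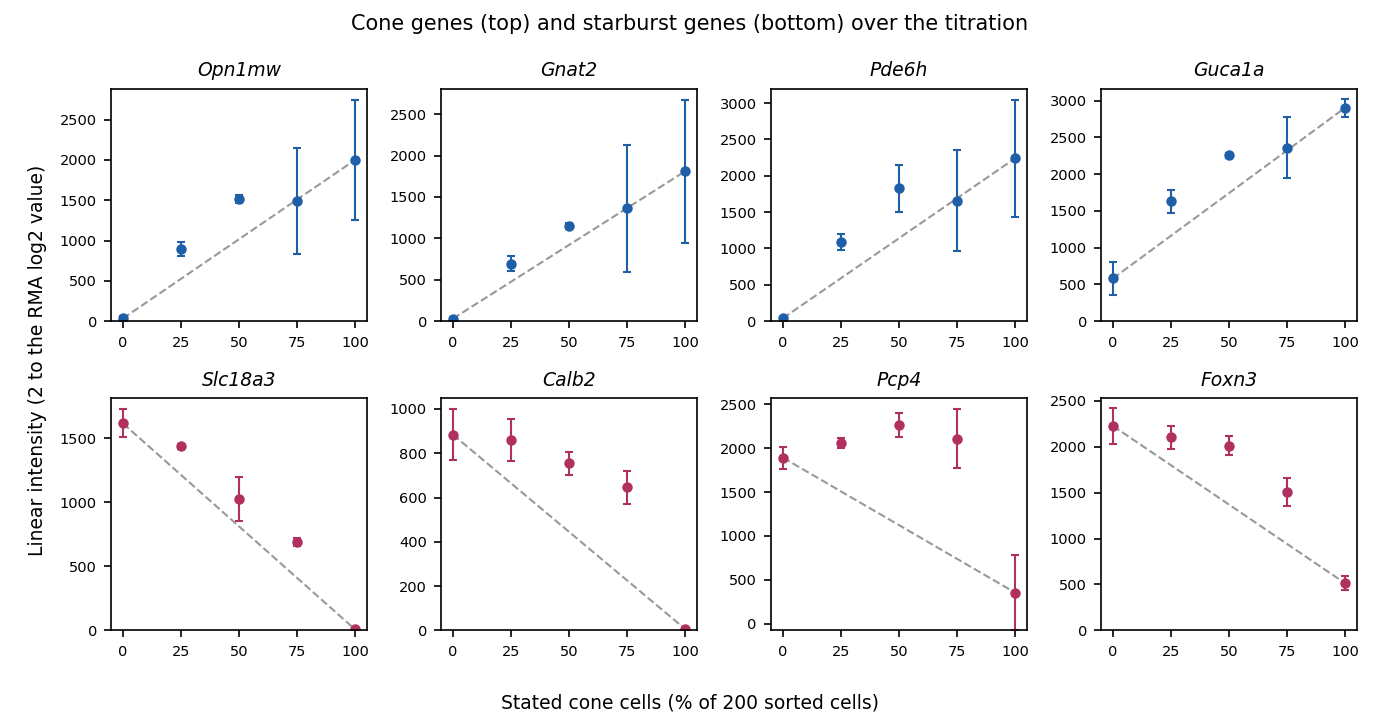
Linear intensity (y axes, 2 to the power of the RMA log2 value) of 4 cone genes (top) and 4 starburst genes (bottom) against the stated cone share in percent of 200 sorted cells (x axes). Points are means of 3 arrays with SD bars, and dashed lines join the pure groups; Opn1mw at 25% stood at 896, and Slc18a3 in pure cones differed from pure starburst by -7.50 on the log2 scale.

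A straight line in cell number was tested on 276 cell-type genes, 101 higher in cones and 175 higher in starburst cells by a log2 fold change of at least 2. A straight-line R2 of at least 0.9 over the 5 group means was found for 152 of them, or 55.1% (Wilson 95% interval 49.2% to 60.8%, which takes the genes as independent, though they are not), with a median R2 of 0.909. Simulated mixtures on a straight line with the spread of these arrays gave 58.2%, and those with a log2 yield ratio of -1 gave 42.1%. The share was 51.5% of cone genes and 57.1% of starburst genes. It was 43.7% without replicate 1 and 39.8% without replicate 2 of every group. Curvature was called by limma in 26 genes, 22 above the line joining the ends, all of them starburst genes, and 4 below it; 86 had an unadjusted p under 0.05. Pcp4 (adjusted p = 0.0010), Slc10a4 (0.0010), the transcription factor Foxn3 (0.0043), the myelin glycoprotein Omg (0.0043) and Calb2 (0.0043) were the most curved. Of the 5 brightest starburst genes, Foxn3, Pcp4, Sparcl1 (0.0266) and Psd3 (0.0425) were curved and Slc18a3 was not (0.134), while the 5 brightest cone genes were not (Guca1a 0.0592, Pde6h 0.261, Opn1mw 0.388, Sag 0.584, Gnat2 0.735). Curvature was called in 0 genes by limma without replicate 2 of every group (55 with an unadjusted p under 0.05) and in 4 without replicate 1. It was called in 48 genes without the third arrays of the groups with cone cells, 23 above and 25 below the line, and in 6 against the share expected from the RNA yield ratio given below.

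Each array was then placed between the pure groups, at 0% for pure starburst and 100% for pure cone, by the medians of the cell-type genes on the linear scale. Mixtures with a stated cone share of 25%, 50% and 75% stood at 18.7% ± 3.69 (SD, n = 3), 38.3% ± 3.83 and 54.6% ± 15.8. The X mixtures with stated shares of 37.5%, 78.5% and 91.5% stood at 11.9% ± 3.22, 55.8% ± 15.7 and 76.1% ± 24.5. In the last of these, replicates 1, 2 and 3 stood at 92.3%, 88.1% and 47.9%. Expressed as a ratio of RNA contributed per cone cell to that per starburst cell, the 9 titration mixtures gave a log2 ratio of -0.85 ± 0.62 (SD, 9 arrays), below 0 on 9 of 9, or 1.81 times as much per starburst cell. The exact two-sided sign-flip p of 0.0039 takes the 9 arrays as independent, though they came from 3 pools. The means of numbers 1, 2 and 3 were -0.57, -0.78 and -1.21, and 3 pools allow no p under 0.25. Correcting by this ratio moved the X mixtures to 19.5% ± 4.85, 68.6% ± 14.3 and 83.7% ± 18.4. Over the 18 arrays that held both cell types, estimated and stated share correlated with Pearson's r of 0.858 (two-sided permutation p = 2e-05) and Spearman's rho of 0.856 (2e-05). These p-values also take the arrays as independent, though they are replicates of 6 mixtures and titration arrays of a number shared a pool. With 2 of the 3 arrays of lowest stated share left out, r was 0.843 to 0.857. Within replicate numbers 1, 2 and 3 (6 arrays each) r was 0.959, 0.975 and 0.882, within the titration 0.880 and within the X mixtures 0.886.

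**Figure D3:**
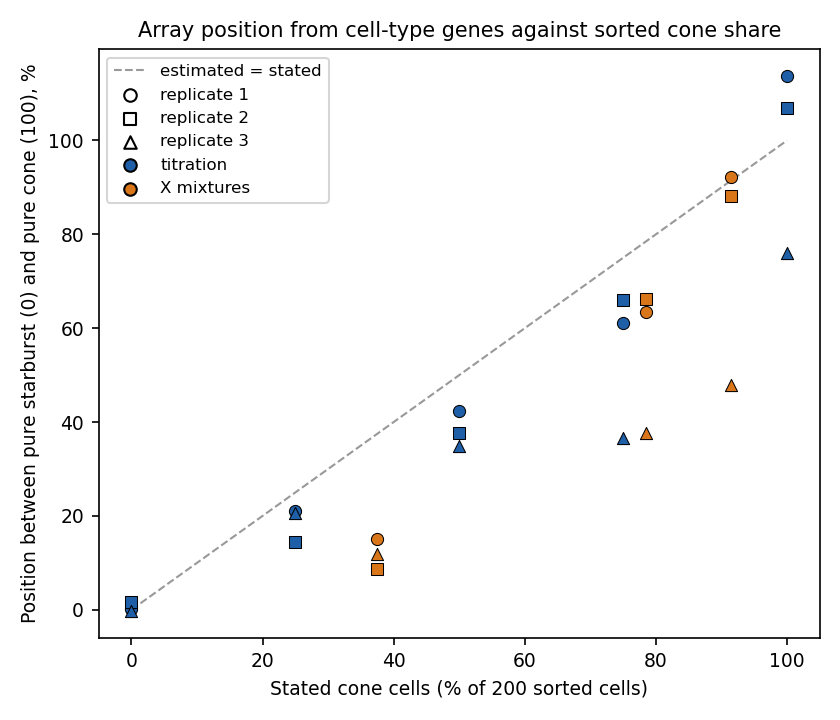
Position of each array between pure starburst (0) and pure cone (100) in percent from cell-type genes (y axis) against the stated cone share in percent of 200 sorted cells (x axis), with 1 point per array and the dashed line for equal values. Blue points are the titration and orange points the X mixtures; the mixture with 75 cone cells stood at 11.9% on average for a stated 37.5%.

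Arrays numbered 3 read low for cone genes in 5 of the 7 groups that held cone cells, where the 101 cone-high genes differed from the other 2 arrays by -0.77 to -1.35. With 50 and 100 cone cells they differed by -0.09 and 0.0041. The cone photoreceptor list averaged 7.98, 7.94 and 6.64 on pure cone replicates 1, 2 and 3, and over the 7 cone-bearing groups the third array lay lower than the mean of the other arrays by a log2 difference of -1.13 ± 0.76 (SD over groups; below 0 in 6 of 7; exact two-sided sign-flip p = 0.031). Rod genes that had not been called between cones and starburst cells lay higher on these arrays by 0.80 ± 0.60 (9 genes; above 0 in 7 of 7 groups; exact p = 0.0156, the smallest that 7 groups allow). With 50, 75 and 100 cone cells the difference was 0.25, 0.28 and 0.14, and with 150, 157, 183 and 200 it was 0.86, 1.00, 1.54 and 1.54. Without sorted cone cells it was 0.23 in the Arc group and -0.28 in the pure starburst group. The other 4 rod genes, which had been called, differed by -0.10 ± 0.23 (3 of 7 above 0), with Sag at -0.26 ± 0.35 (2 of 7). All 13 rod genes lay higher by 0.52 ± 0.42 (7 of 7; exact p = 0.0156). These p-values take the groups as independent, though by the design the titration groups of a number shared a pool. Number 3 was singled out because cone genes read low on it, so the p-value of the cone list tests the values that picked it. Gnb1, which the rod list holds as a transducin subunit, read 7.76, 7.56 and 9.52 on the pure cone arrays, the cyclic nucleotide channel Cnga1 5.24, 4.61 and 8.02, and Pde6b 5.81, 6.24 and 8.50. Over the 7 groups Reep6 differed by 0.50 ± 0.83 (4 of 7 above 0), Nrl by 0.20 ± 0.22 (6 of 7) and Slc24a1 by 0.15 ± 0.44 (4 of 7). Pan-photoreceptor genes lay lower (-0.33 ± 0.26, 6 of 7, exact p = 0.031), as did oxidative phosphorylation (-0.22 ± 0.22, 6 of 7, exact p = 0.031) and immediate early genes (-0.08 ± 0.05, 7 of 7, exact p = 0.0156). Starburst (0.12 ± 0.09, 7 of 7, exact p = 0.0156) and horizontal cell genes (0.13 ± 0.12, 6 of 7, exact p = 0.0469) lay higher. The sign-flip p-values of lists were not adjusted over the 31 lists compared, the cone and rod lists included. They exclude chance for none of these lists, and the small shifts may be due to chance. Bipolar genes differed by 0.27 ± 0.33 (exact p = 0.0938) and Muller glia genes by 0.14 ± 0.51 (exact p = 0.5). Without the third arrays of those groups, which was run after this was seen, 1067 genes were called between cones and starburst cells (457 higher and 610 lower in cones), 464 between the Arc cells and starburst cells and 1276 between the Arc cells and cones. The bipolar (camera 0.538), ionotropic glutamate receptor (0.0566), glycolysis (0.26) and ribosomal protein (0.118) lists were then no longer called between cones and starburst cells, nor the vascular list (0.145) between the Arc cells and cones.

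**Figure D4:**
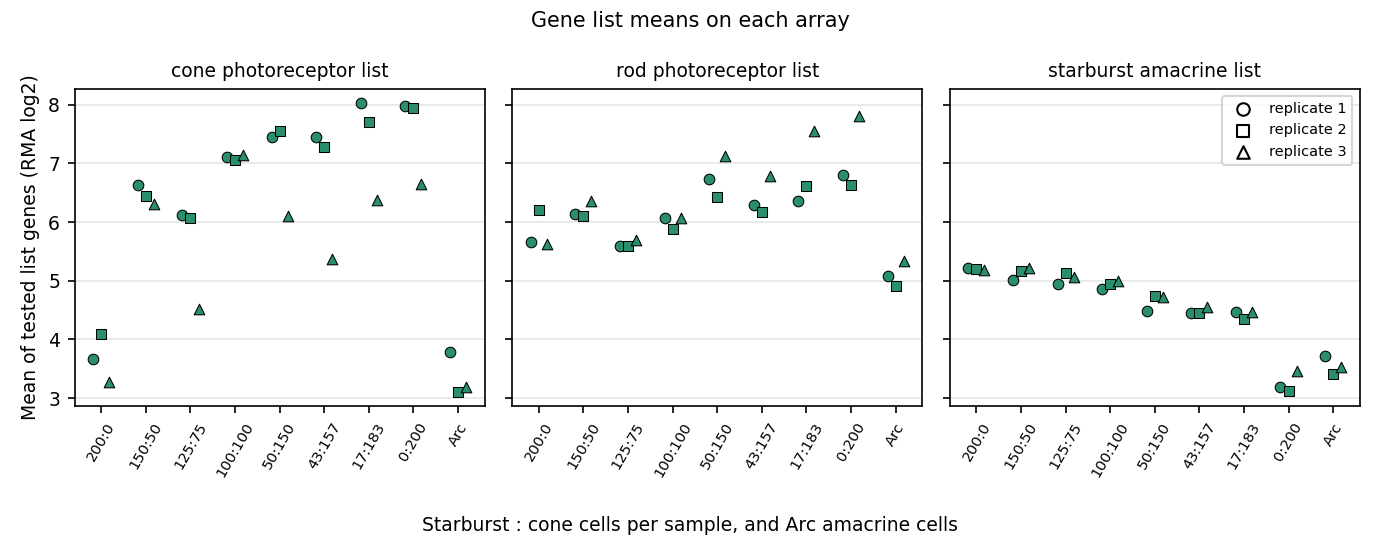
Mean RMA log2 value of the tested genes of the cone, rod and starburst lists (y axes) on each of the 27 arrays, grouped by starburst and cone cells per sample with the Arc amacrine cells last (x axes). Marker shapes give the replicate number; on pure cone arrays the rod list read 6.80, 6.63 and 7.80 and the cone list 7.98, 7.94 and 6.64 for replicates 1, 2 and 3.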

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

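The tests of the third-numbered arrays and of the mixtures' low cone readings were chosen only after those results were seen, while the splits of the arrays were planned. Probe sets outside the gene tests carried signal as well. Among the 735 probe sets that name several genes, limma called 31 between pure cone and pure starburst arrays, 11 higher in cones and 20 higher in starburst cells. Among the 2166 probe sets with no listed gene it called 52, 23 higher in cones and 29 in starburst cells. No explanation was tested for these.

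Cone genes were low on the third-numbered arrays of the groups with cone cells, by -1.13 on average for the cone list. A general loss of signal on those arrays that lowers all genes alike could not be tested, since normalization between arrays would remove it. The 13 rod genes, each brighter than the median value, averaged higher there by 0.52 ± 0.42 (SD over 7 groups, 7 of 7). The fall was thus not shared by all genes above that level, which is also the level of the filter for dim genes. Rod cells or rod RNA among the sorted cone cells may account for part of the pattern and stay open. The 9 rod genes not called between the pure groups lay higher by 0.80 ± 0.60 (7 of 7). The difference was 0.86 to 1.54 with at least 150 cone cells and 0.14 to 0.28 with 50 to 100. On the third Arc and pure starburst arrays, which held no sorted cone cells, it was 0.23 and -0.28. The 4 rod genes called between the pure groups did not lie higher (-0.10 ± 0.23, 3 of 7, Sag by -0.26), nor did pan-photoreceptor genes (-0.33 ± 0.26, 6 of 7 below 0), and the GFP gate was meant to exclude rods. Not being called depends partly on the spread that high values on the number 3 arrays bring, the titration groups of a number shared a pool, and another state of the cone cells, or the inherited photoreceptor degeneration that the labels name for the background of some mice, stays open, untested.

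The titration mixtures read below their stated cone share, with a log2 yield ratio of -0.85. For them a shortfall on the third arrays as the whole cause is argued against, since the arrays numbered 1 and 2 gave -0.67 ± 0.26 (SD, 6 arrays from 2 pools, with means of -0.57 and -0.78). Of the X mixtures, arrays 1 and 2 averaged 11.9% for a stated 37.5% and 64.8% for a stated 78.5%. With 183 cone cells they averaged 90.2% for a stated 91.5%, so that its low reading rested on the third array (47.9%). Compression of high values as the cause for the gene set as a whole is argued against as well, since cone-high genes alone, which it would push above the stated share, gave -0.94 ± 0.59 (SD over 3 pools, below 0 in 3 of 3). It stays open for the brightest genes, where Opn1mw, Pde6h, Guca1a and Gnat2 lay above the line and Sag below it, none with curvature called by limma (adjusted p of 0.0592 to 0.735). More RNA per starburst cell than per cone cell may account for the low readings, with -0.79 ± 0.35 from starburst-high genes alone (SD over 3 pools, below 0 in 3 of 3, where no p under 0.25 is possible), though miscounted or lost cone cells would give the same values.

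Other splits of the same arrays were counted. For 3 arrays against 3 only 10 splits exist, too few for a share under 0.05, and in each comparison 1 split, the real one, gave its count. The real count of genes and the highest other were 1048 and 2 for pure cone against pure starburst, 442 and 1 for Arc amacrine against pure starburst, 1286 and 1 for Arc amacrine against pure cone, 6 and 1 for the mixture with 50 cone cells and again for that with 75, and 174 and 13, 192 and 7, and 91 and 19 for those with 150, 157 and 183. For the gene lists they were 15 and 12, 13 and 8, and 13 and 10 in the first 3 comparisons. For the slope over the titration, 1 of 100 drawn splits of the 15 arrays, the real one, gave 1020 genes, and the highest other gave 117. A random order of the arrays was thus unlikely to give this count. The draws took the arrays as independent, though they came from 3 pools, so chance is not excluded by them. For curvature, 5 of 100 gave the real 26 or more and the highest other gave 117. These splits move pure arrays into the middle groups, which bends the line by itself, so that they say nothing about chance.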

How the results depend on the processing

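The third arrays of the groups with cone cells, and Pigq in the glycolysis list, were left out only after the results were seen, and the other alternatives were planned and run. Of the main results, 250 values under an alternative stayed within 1.5 times the count or within the spread and 45 moved. Named genes reversed in 0 comparisons with limma, while 7463 were the same, 205 weaker and 80 stronger, and list calls were the same in 485, weaker in 48 and stronger in 25. No scaling moved the median of all genes by more than 0.1. Signal over background limits dim genes, since the filter lay at 2.83. The cause of these moves was not tested. In the order of 50 and 75 cone cells against pure starburst (6 and 6 genes), the counts were 21 and 1 with only the 2 groups compared, 18 and 11 with array weights, 3 and 1 at an adjusted p under 0.01, and 35 and 23 without the third arrays, and for 50 cone cells 10 with the filter at the 75th percentile and 11 with quantile normalization again. Leaving out 1 array gave 3 to 11 for 50 cone cells (3 without mixture replicate 1 or 2, 11 and 10 without pure starburst replicates 2 and 3) and 2 to 9 for 75 (3, 9 and 2 without mixture replicates 1, 2 and 3). Against pure cones, only the 2 groups gave 36, 24 and 8 with 50, 43 and 17 starburst cells, and an adjusted p under 0.01 gave 105 with 43. With no fold threshold, 1752 genes differed between pure cone and pure starburst, 715 between Arc amacrine and pure starburst, 2207 between Arc amacrine and pure cone, and 1974 followed the cone share. The mixture with 75 cone cells (11.9%) read 8.08% with quantile normalization again, 16.0% from genes with a fold of at least 1, 6.81% from cone-high and 16.9% from starburst-high genes. The share with an R2 of at least 0.9 (55.1%) was 46.1% with quantile normalization again and 39.8% to 55.9% without 1 replicate number. The count of curved genes (26) was 43 with quantile normalization again, 15 and 17 from folds of at least 1 and 3, 2 from cone-high genes, 6 against the share expected from the yield ratio, 48 without the third arrays (23 above and 25 below the line), and 0 to 26 without 1 replicate number (limma; 4 without number 1; 0 without number 2, with 55 at an unadjusted p under 0.05). List tests (41) gave 19 calls with an estimated correlation (9, 3 and 7) and 36 without Pigq (10, 13 and 13), and fry gave 24 for Arc amacrine against pure cone. The replicate block gave 1060, 434 and 1302 genes between the cell types, 8, 7, 195, 214 and 104 for the mixtures with 50, 75, 150, 157 and 183 cone cells, 1017 for the slope and 36 curved genes.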

Other observations

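The genes and tests of this part were chosen only after values were seen. Otx2 and Crx, which drive photoreceptor genes, were higher in pure cones than in pure starburst cells by 1.71 ± 0.23 (SE, n = 3 arrays per group; limma adjusted p = 1.7e-05) and 1.61 ± 0.22 (2.3e-05), and differed by -2.85 and -1.73 in the Arc cells against cones. Pax6, a factor of amacrine cells, was lower in cones than in starburst cells (-2.17 ± 0.28, 1.0e-05) and did not pass between the Arc cells and starburst cells (0.80 ± 0.28, 0.115). The dopamine receptor Drd4 was higher in cones than in starburst cells (2.82 ± 0.47, 1.9e-04), and the neuropeptide Npy was lower (-4.11 ± 0.24, 5.8e-11).

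Sex-linked genes differed between replicates of a group. The Y-linked Eif2s3y read 1.62, 5.06 and 3.70 on pure cone replicates 1, 2 and 3, and Xist, which is expressed from the inactive X, 7.57, 5.47 and 6.11. Eif2s3y was highest on number 2 in the 4 groups with at least 150 cone cells and on number 3 in the other 5 groups, with 3.49, 2.33 and 3.23 at 50, 75 and 100 cone cells. No explanation was tested, and the sex of the mice was not analysed here.

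The mixture with 75 cone cells stood at 11.9% and that with 50 at 18.7%, against shares of 37.5% and 25% by the labels, which do not say how the cells of the X mixtures were counted (exact two-sided permutation p = 0.2, where the smallest possible is 0.1). Its log2 yield ratio was -2.19 ± 0.46 (SD, 3 arrays), against -0.85 over the 9 titration arrays (exact two-sided permutation p = 0.0136, which takes the arrays as independent though they may share pools). Bright cone genes reached further than dim ones with 50 cone cells: the brightest 25% of the 101 genes had a median of 24.1% and the dimmest 16.4%. With 183 cone cells these medians were 88.2% and 59.0%. Spearman's rho over genes, between the level in the own pure group and the percent reached, was 0.23 to 0.43 for cone genes over all mixtures. For starburst genes it was 0.08 to 0.32. No p-value was taken for these differences.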
